A study of Mus musculus with 104 samples.

How the data were processed

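The series holds 104 samples in 50 groups: mouse embryonic stem cells (mESCs), oocytes and morulae, wild type (WT) or knockout (KO) for Fto, which encodes an RNA demethylase of N6-methyladenosine (m6A). The mESCs were kept in serum with LIF and the GSK3 and MEK inhibitors CHIR99021 and PD0325901, per the labels' protocols. Chromatin-associated RNA (caRNA) depleted of ribosomal RNA and polyadenylated mRNA were enriched with an m6A antibody (3 and 2 libraries per genotype). ChIP used 9 antibodies with 2 libraries per genotype. Nuclear RNA was taken at 0 h and 6 h of actinomycin D (5 µg/mL), and RNA labelled with 0.5 mM 5-ethynyl uridine for 10, 30 or 60 min was captured as nascent RNA, with 2 libraries per group. Germinal vesicle (GV) oocytes, metaphase II (MII) oocytes and morulae had 2 libraries per genotype, and ATAC-seq came as 1 pooled peak list per genotype. The labels do not say whether replicates were separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical. The title of the KO morula samples calls them DKO; they are treated here as Fto KO, the genotype their other labels give.

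The deposited RNA tables hold estimated counts per gene, made with featureCounts from reads trimmed with Trimmomatic and aligned to mm10 with HISAT2 2.1.0, per the submitters' processing notes. The authors' values include fractions of a read, so reads shared by similar genes were divided, and they were rounded to whole counts here. The strand and multimapping options are not given in the sources used here. The deposited m6A peak lists, called per strand on mm10 with MACS2 per the submitters' processing notes, give for each peak a score, and the authors' input and antibody signal with their ratio as a fold; how score and signal were scaled is not given in the sources used here. The deposited ChIP lists (Bowtie2 and MACS2 on mm10) and ATAC lists (Trim Galore, Bowtie2, deepTools and MACS2 on mm9) give a fold over the local background, a -log10 q and a score made from it, with tools per the submitters' processing notes. The thresholds of the peak calls and the ChIP controls are not given in the sources used here. Coordinates below are mm10 and 1-based; ATAC lists were never compared with the others, because their build differs. Some ChIP lists also hold sequences named as Drosophila, whose use the labels do not describe.

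Choices of groups, contrasts, gene lists, named-gene rule and most alternatives were made before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled by TMM, and tested by the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Nuclear, nascent and GV tables were each fitted with all of their groups, and MII oocytes and morulae, which share a table, were fitted together. There were 10 contrasts: KO against WT in nuclear RNA at 0 h and at 6 h, 6 h against 0 h in WT, the difference between KO and WT in that change (decay difference), nascent RNA as the mean over the 3 labelling times, the difference between its 60 and 10 min effects, GV, MII and morula, and the difference between the morula and MII effects. The 92 ERCC transcripts and the m6A control RNAs stayed out of library sizes and tests. Replicate numbers are shared numbers, not stated pairs, so no block was used in the main fits. A replicate block was an alternative, also in nuclear RNA, where residuals of equal numbers correlated at 0.172 to 0.222.

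Depth, in gene counts (M for mega), was 17.1 to 21.6 M in nuclear, 10.4 to 22.6 M in nascent, 35.0 to 41.4 M in GV, and 14.3 to 35.1 M in MII and morula libraries. ERCC counts made up 0.71 to 1.54% of nuclear, 6.98 to 40.0% of nascent and 0.69 to 0.84% of GV counts, and up to 1.22% in MII oocytes and morulae. MII libraries held too few ERCC counts (4 or fewer) for scaling. Between replicates, log2 CPM (counts scaled to library size) correlated at 0.980 to 0.994.

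The rule for named genes took Fto in every sample and, per contrast, the 5 largest increases and 5 largest decreases past the threshold, with mean log2 CPM of at least 2 over the fitted samples, a gene symbol other than a clone or Gm number, and every KO value on the same side of every WT value. It added up to 4 members of each list with the smallest adjusted p. For peaks it was the 5 genes with the highest mean score for m6A, and up to 3 per antibody and direction for ChIP, by regions at the gene start. Where one genotype had 3 counts or fewer, the ratio is given with its exact 95% counting interval, or as a bound against a floor of 3 counts over the group where it had none; these intervals and floors cover counting error only.

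The 23 gene lists were m6A writers, erasers and readers; naive pluripotency; formative and primed pluripotency; 2-cell and zygotic activation genes; primitive endoderm; mesoderm; neuroectoderm; trophectoderm; fibroblast feeder markers; oocyte and maternal effect genes; cumulus and granulosa cell markers; heterochromatin and LINE-1 repressors; nuclear exosome, NEXT and PAXT decay factors; cytoplasmic deadenylation and mRNA decay factors; immediate early genes; p53 targets; imprinted genes; mitochondrially encoded genes; nuclear long noncoding RNAs; cytosolic ribosomal proteins; innate antiviral response; Fto neighbours on the chromosome; and germline genes sensitive to DNA methylation. Lists with at least 5 tested members were tested in 6 contrasts with camera (limma 3.58.1, inter-gene correlation 0.01), adjusted over the lists of a contrast. Members past the threshold were counted over all genes and again adjusted over the list alone.

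Peaks of all lists of an assay were joined into regions where they overlapped by 1 bp, per strand for m6A. A region of one genotype only had a peak in every list of that genotype and in no list of the other. Gene places used Ensembl gene models on mm10; 54409 of 54446 gene names of the count tables were matched. ChIP lists were compared by covered length with an exact permutation test, which with 2 against 2 libraries cannot pass the threshold. Genes with one-genotype regions within 1000 bp of their start (ChIP) or over their body (caRNA m6A) were tested as sets with camera, against genes with any region of that assay. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for peaks and figures.

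The count tests were tested on simulated data drawn from the real means and library sizes with 200 changed genes. At log2 changes of 0.5, 1 and 2 they recovered 20.8, 56.1 and 81.8% of genes in nuclear RNA at 0 h, 50.8, 93 and 94.1% in nascent RNA, and 60.9, 81.8 and 96.9% in GV oocytes. They recovered 25.7, 68.3 and 77.8% in MII oocytes, 16.4, 42.9 and 52.9% in morulae, and 1.5, 34.7 and 80% for the decay difference. False genes made up 5.79 to 11.88% of calls. A planted list of 30 genes was called in each of the 6 contrasts, and peak regions planted in one genotype were all recovered.

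Alternatives were edgeR's RLE scaling, DESeq2 1.42.0, no filter on low counts, a replicate block, leaving out each library, fits with only the contrast's groups, a stricter peak threshold (-log10 q of at least 5.0, taken for m6A lists from the score on the caller's usual scale), a stricter overlap (50%), equal numbers of peaks per list, merging of peaks within 1000 bp, camera with an estimated correlation, and fry. ERCC scaling (for morulae in a fit without the MII libraries), nascent RNA without the 10 min libraries, and the level of named genes in MII oocytes alone were chosen after seeing the data. Input and antibody columns beside the m6A lists were not used here, and repeats such as LINE-1 were not analysed here for want of a repeat annotation.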

Results

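The comparisons cover KO and WT mESCs, GV and MII oocytes and morulae, with 2 libraries per group, 3 for caRNA m6A and 1 pooled list per genotype for ATAC. Fto RNA was lower in every KO library than in every WT library of the same group, so the labels fit the targeted gene. In nuclear RNA at 0 h, Fto stood at 39.8 and 41.0 CPM in KO and 77.9 and 80.6 CPM in WT mESCs. At 6 h of actinomycin D it stood at 30.5 and 28.0 CPM against 100.3 and 104.8 CPM. In nascent RNA it stood at 98.98 and 100.5 against 118.1 and 121.9 CPM after 10 min. It stood at 93.8 and 96.7 against 120.5 and 128.9 CPM after 30 min, and 61.6 and 60.4 against 70.1 and 67.9 CPM after 60 min. KO and WT levels were 4.32 and 4.57 against 12.4 and 11.5 CPM in GV oocytes, 5.78 and 3.63 against 8.82 and 11.3 CPM in MII oocytes, and 2.34 and 3.47 against 9.23 and 6.59 CPM in morulae. By the edgeR quasi-likelihood test, Fto changed by a log2 of -0.97 in nuclear RNA at 0 h (SE 0.07, n = 2 per group, adjusted p = 5.00e-08), -1.43 in GV oocytes (SE 0.12, adjusted p = 6.00e-11), -1.10 in MII oocytes (SE 0.28, adjusted p = 0.00682) and -1.45 in morulae (SE 0.32, adjusted p = 0.00297). The fall in nascent RNA was smaller (log2 -0.28, SE 0.03), and with ERCC scaling it no longer passed. Fto spans chromosome 8 from 91313525 to 91668439 (mm10), and which part of it was removed is not given in the sources used here.

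**Figure D1:**
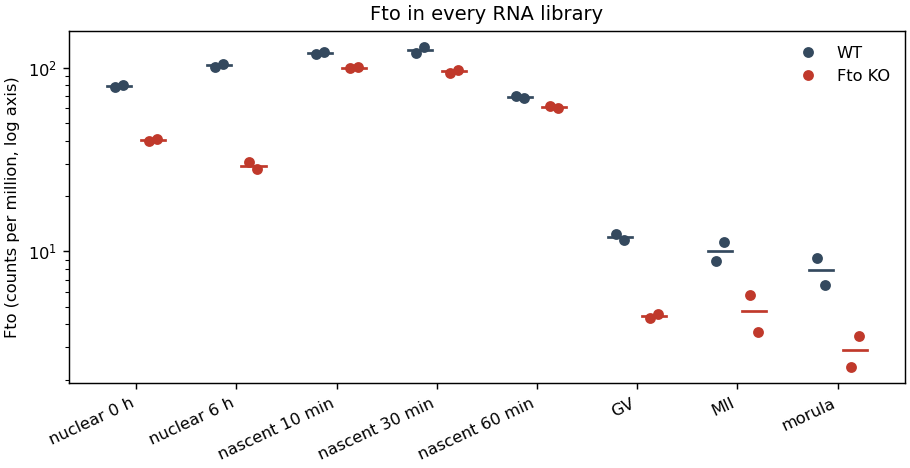
Fto in CPM in each of the RNA libraries, WT and KO side by side, with group means as bars. KO points lie below WT points in all 8 pairs of groups, with the smallest gaps in nascent RNA.

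Chromatin-associated RNA held m6A peaks called in one genotype only at many places, in KO as well as WT cells. RNA level and antibody enrichment were not separated from methylation here. The peak on the m6A control RNA had a mean fold of 2.33 in KO lists and 1.61 in WT lists. Of 136826 regions, 15007 (11.0%) were in every list, 1934 (1.41%) in all 3 KO lists and no WT list, and 2763 (2.02%) in all 3 WT lists and no KO list. By score, the KO-only genes named by the rule were Pdia4 (a disulfide isomerase of the endoplasmic reticulum; chromosome 6, 47796298 to 47797036), N4bp1 (an RNase that limits inflammation), Lbhd1, Oxr1 (oxidation resistance) and Zfp317 (a zinc finger factor). The WT-only genes were Atpif1 (inhibitor of ATP synthase; chromosome 4, 132530562 to 132530931), Gadd45gip1 (a mitoribosome subunit), Hspa8 (the constitutive HSP70), Chd6 (a chromatin remodeller) and Actb (beta-actin).

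Within Fto itself, whose RNA was lower in KO cells, 9 regions were in all WT and no KO lists, from 91313398 to 91667291. Another 3 were in all KO and no WT lists, at 91324633 to 91325103, 91325426 to 91325719 and 91559757 to 91559918. KO-only regions lay in 1147 genes. Of 15124 genes with any caRNA m6A region and tested in nascent RNA, 1052 had a KO-only and 1553 a WT-only region. The gene lists were not tested against these shares. KO-only regions touched 3 of 25 m6A factors (Fto, the cap methyltransferase Pcif1 and the writer scaffold Virma) and the naive pluripotency genes Fgf4 and Klf4. They also touched 4 of 30 nuclear long noncoding RNAs (Airn, Platr3, Pvt1 and Tug1) and 0 of 35 2-cell genes. Only 16 of these 2-cell genes were tested in nuclear RNA at 0 h. WT-only regions lay in 1633 genes, including 4 of 25 m6A factors (Fto, Hnrnpc, the catalytic writer Mettl3 and Wtap), 4 of 32 heterochromatin factors (Atrx, Chaf1b, Setdb1 and Suv39h2). They also held 3 of 26 nuclear decay factors (Exosc10, Rbm7 and Zcchc8) and 3 p53 targets (Ccng1, Mdm2 and Trp53inp1). KO peaks lay in introns slightly less often (34.6% ± 0.29) than WT peaks (35.6% ± 0.23; mean ± SD, n = 3 lists; exact permutation p = 0.1, the smallest that 3 against 3 allows), and shares in exons (36.0 and 35.2%, p = 0.4) and outside genes (29.4 and 29.3%, p = 0.7) differed little. Dropping a list loosens the rule: KO-only counts were 4023, 4304 and 3589 without KO lists 1, 2 and 3 and 2919 and 3036 without WT lists 1 and 2, and WT-only counts were 5437, 5280 and 5570 without WT lists 1, 2 and 3.

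In polyadenylated mRNA the 2 genotypes held similar numbers of one-genotype m6A regions. Of 22448 regions, 890 were in both KO lists and no WT list (607 genes) and 918 in both WT lists and no KO list (787 genes). The KO-only genes with the highest scores were Imp3 (U3 snoRNP processing of ribosomal RNA), Sec62 (protein translocation), Tbx3 (a pluripotency transcription factor), Mrps7 (a mitoribosome protein) and Cdkn2aip (a regulator of p53). The WT-only ones were Mrto4 (ribosome assembly), Mrps34, Thrap3 (splicing), Thumpd3 (tRNA methylation) and Aff4 (the super elongation complex). The gene lists were not tested against the share of all genes here. KO-only regions touched 3 of 35 2-cell genes (BB287469, Tdpoz3 and Zscan4b). WT-only regions touched the m6A factors Alkbh5, Fto, Pcif1 and Wtap, the naive genes Klf5, Lifr, Prdm14 and Tet1. They also touched the heterochromatin factors Daxx, Ehmt1, Resf1 and Setdb2, and the imprinted Nespas, Snrpn, Snurf and Usp29. Exons held 72.1% ± 1.59 of KO and 76.0% ± 2.17 of WT peaks (mean ± SD, n = 2; exact permutation tests of 2 against 2 cannot pass 0.05). Some lists of different genotypes shared more: KO list 1 and WT list 2 alone held 2642 regions, and other mixed pairs 264 to 832. The split by genotype gave 1808 one-genotype regions in all, and the highest other split 2906. Genes named above from these regions thus cannot be told from differences between lists. The lists were uneven, with 13518 and 6540 peaks in KO and 9834 and 13394 in WT. With equal numbers of peaks per list the counts were 491 KO-only and 470 WT-only regions. Without KO list 1 they were 2144 and 3510, without WT list 2 1931 and 3423, KO-only 3983 without KO list 2, and WT-only 4350 without WT list 1.

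Nuclear RNA of KO mESCs before actinomycin D carried much more of single transcripts such as Ankrd31 and Myo7a. Ankrd31, needed for meiotic recombination, rose by a log2 change of 6.28 (SE 0.21; chromosome 13, 96748272 to 96910039), Myo7a, a motor of sensory hair cells, by 4.17 (SE 0.18). The germline RNA export factor Nxf3 rose 16.4-fold and the testis chaperone Clgn 10.0-fold. Tchh, a hair follicle protein, changed by log2 -3.81, Mios of the amino acid sensing complex GATOR2 fell by 5.36-fold, and the carbonic anhydrase Car2 by 3.88-fold, beside Cyp2b23 (log2 -2.28) and the kallikrein Klk10 (log2 -1.94). In all, 3711 of 18514 genes passed (1945 higher, 1766 lower, 5860 at unadjusted p < 0.05; 2 libraries per genotype), and 374 rose and 331 fell at least 2-fold. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 4.66e-07 for Ankrd31 and 2.65e-10 for Tchh. The count was 2291 with ERCC scaling, 2243 without KO library 1, 2418 without KO library 2 and 2434 without WT library 2.

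Ribosomal protein transcripts were higher and nuclear long noncoding RNAs lower in the nuclear RNA of KO cells. Mitochondrial transcripts made up 13.93 and 11.39% of gene counts in KO and 12.02 and 10.19% in WT libraries at 0 h. The purity of the nuclear fraction was not tested. Cytoplasmic RNA left in it is thus not separated from a change within nuclei. Of 56 ribosomal protein genes, 14 were higher and 1 lower, or 8 and 1 with ERCC scaling (17 past when adjusted over the list alone), led by Rps18 (log2 0.72) and Rpl32 (0.53). As a group they gave a camera adjusted p = 1.39e-05 (adjusted p = 0.832 with an estimated correlation). Of 27 long noncoding RNAs, 13 were lower, including Firre (log2 -0.57), which anchors the inactive X, Kcnq1ot1 (-0.37) and Tug1 (-0.48), and 2 were higher (15 adjusted over the list alone; camera adjusted p = 7.35e-05, adjusted p = 0.643 with an estimated correlation). The mitochondrial list had 3 of 15 higher, or 7 with ERCC scaling, with mt-Atp8 at log2 0.92 (3 adjusted over the list alone, camera adjusted p = 7.35e-05, adjusted p = 0.688 with an estimated correlation). Fibroblast feeder markers moved with them: 5 of 16 were higher, among them Mmp2 (log2 1.51), Acta2 (0.59) and Col1a1 (0.30), and 1 lower (7 adjusted over the list alone; camera adjusted p = 0.0444, adjusted p = 0.643 with an estimated correlation).

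Other lists of nuclear RNA did not pass as groups in the fit without a replicate block, though members did. With the block, the trophectoderm, heterochromatin and nuclear decay lists passed (camera adjusted p = 0.049 each). Pluripotency genes went both ways: Tdgf1 (log2 0.56) rose while the LIF receptor Lifr (-0.57), Tet2 (-0.29) and Sall4 (-0.30) fell, 6 higher and 8 lower of 30, or 2 and 3 with ERCC scaling (17 adjusted over the list alone). Imprinted genes split as 9 higher and 10 lower of 32 (20 adjusted over the list alone), with the noncoding H19 (log2 1.57) and Peg10 (1.00) up and Peg3 (-1.08) down. Trophectoderm genes were 6 higher, led by Gata2 (log2 1.52), Krt8 (1.55) and Dppa1 (4.11), and 1 lower of 15 (8 adjusted over the list alone; camera adjusted p = 0.0717). Heterochromatin and LINE-1 repressors were 2 higher and 8 lower of 29, or 0 and 2 with ERCC scaling (11 adjusted over the list alone), with Fam208a of the HUSH complex (log2 -0.57) and Dnmt1 (-0.32) down. Among m6A factors the demethylase Alkbh5 rose (log2 0.47) and the nuclear reader Ythdc1 fell (-0.29), 3 higher and 6 lower of 24, or 1 and 1 with ERCC scaling (10 adjusted over the list alone). Nuclear decay factors were 4 higher and 7 lower of 24 (2 and 2 with ERCC scaling), formative genes 5 and 2 of 15, and antiviral genes 3 and 1 of 16, with Tmem173 (STING, log2 1.27) up (12, 9 and 4 adjusted over the list alone). Germline genes were 2 and 2 of 19, oocyte genes 3 and 1 of 11, neuroectoderm genes 2 and 3 of 12 and mesoderm genes 1 and 0 of 10 (5, 4, 6 and 1 adjusted over the list alone).

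Among the 5 largest named decreases in WT nuclei over 6 h of blocked transcription, 4 were replication-dependent histone genes. Hist1h2ac fell by 26.0-fold, Hist2h2ac by 24.3-fold, Hist1h2ah by 24.0-fold and Hist1h3a by 22.1-fold, and Mir291b, of a pluripotency microRNA cluster, was 136 times lower (counting interval 37.4 to 1130). In WT 9343 genes passed relative to the other genes (4453 higher, 4890 lower), but scaled to ERCC spikes the median of all genes moved by -0.997 log2 and 12749 fell while 458 rose. KO against WT at 6 h gave 5531 genes (3162 higher, 2369 lower), or 977 higher and 4229 lower with ERCC scaling (median -0.27). Reads of histone genes are shared between near-identical copies, so single members are uncertain.

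Over 6 h of actinomycin D, Socs3 went down further and Hist1h3b less far in KO nuclei than in WT nuclei, relative to the other genes. The log2 change in KO minus that in WT was -1.43 (SE 0.27) for the AP-1 subunit Jun, -1.39 (SE 0.31) for the apoptosis regulator Phlda1, -1.13 for Snhg6, -1.03 (SE 0.17) for the JAK-STAT inhibitor Socs3 and -0.94 for the matrix protein Tnc (2 libraries per group). Jun and Phlda1 went down in KO and up in WT nuclei, while Tnc went up in both and less in KO. Hist1h3b (log2 1.55, SE 0.20), Hist1h4d (1.19), the linker histone Hist1h1b (1.15) and the sialyltransferase St6galnac6 (1.28) had differences the other way. The difference passed for 135 genes (90 higher, 45 lower; 2501 at unadjusted p < 0.05), with adjusted p = 0.00124 for Hist1h3b and 0.0236 for Jun (edgeR quasi-likelihood). With ERCC scaling it passed for 47 (5 higher, 42 lower, median -0.24). Neither fit holds a replicate block. Residuals of equal replicate numbers correlated at 0.172 to 0.222 in nuclear RNA, and a block raised the count above 135, as given below. The pluripotency factor Sox2 (log2 -0.67) and Pou5f1 (0.41) differed in opposite directions.

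Fibroblast feeder markers had lower changes over 6 h in KO nuclei, relative to the other genes. Of 16, 4 passed, or 3 with ERCC scaling, and 9 adjusted over the list alone (camera adjusted p = 3.64e-09, adjusted p = 0.157 with an estimated correlation). The 4 were Col1a1 (log2 -0.65), Col1a2 (-0.57), Fn1 (-0.23) and Acta2 (-0.75), each going up relative to the other genes in both genotypes and less in KO. Immediate early genes had 2 of 16 with a lower change in KO, Jun and Ier2 (log2 -0.77), and 5 adjusted over the list alone (camera adjusted p = 8.55e-06, adjusted p = 0.345 with an estimated correlation). Primitive endoderm genes had 2 of 13 with a smaller relative rise, the basement membrane genes Sparc (log2 -0.33) and Lamc1 (-0.25), but 0 with ERCC scaling, and 4 adjusted over the list alone (camera adjusted p = 4.53e-04, adjusted p = 0.345 with an estimated correlation). Trophectoderm genes had 1 of 15 with a lower change, Lrp2 (log2 -0.43; 0 of 15 with ERCC scaling; 1 adjusted over the list alone; camera adjusted p = 0.031, adjusted p = 0.402 with an estimated correlation). The other called list was mitochondrial, of which 0 of 15 passed and 0 adjusted over the list alone (median log2 -0.21, camera adjusted p = 0.00546, adjusted p = 0.779 with an estimated correlation). Single libraries decide much of this count, which was 65 without KO 0 h library 1, 23 without KO 0 h library 2, 41 without WT 0 h library 1, 18 without WT 6 h library 1 and 21 without WT 6 h library 2.

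Nascent RNA of KO mESCs rose for an antigen-processing tag, a meiotic gene and a sensory myosin, and fell for an ion channel and a hair protein. Ubd, a ubiquitin-like tag for degradation, had 937 counts in KO and 1 in WT (ratio 923, counting interval 165 to 36500). Ankrd31 rose 82.6-fold and Myo7a 20.5-fold as they did in nuclear RNA, and Kng2 (a kininogen) and Fam169b rose 6.88-fold and 5.65-fold. Trpm1, a retinal channel, fell by 12.7-fold, Tchh by 8.46-fold, Mios by 4.49-fold, the RNase P RNA Rpph1 by 4.22-fold and the progestin receptor Paqr8 by 4.16-fold. Over the mean of the labelling times 7818 of 20129 genes passed (3686 higher, 4132 lower; 562 up and 251 down at least 2-fold), with adjusted p = 1.06e-29 for Ubd (edgeR quasi-likelihood, 6 libraries per genotype). ERCC scaling moves the median of all genes by -0.20 log2 and leaves 1469 genes (513 higher, 956 lower), while the 10 min libraries alone moved the other way (0.22). The log2 ratio of gene to ERCC counts differed between replicates, such as 1.28 and 0.88 in KO and 1.24 and 0.59 in WT at 10 min. ERCC scaling adds this spread, so nascent calls lost with it, here and in the lists below, do not show that a gene was unchanged.

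Nascent RNA of 2-cell stage genes rose in KO cells. In nuclear RNA at 0 h their median log2 change was 0.304, with 0 of 16 higher and 1, Tdpoz5, lower (1 adjusted over the list alone, camera adjusted p = 0.805). The difference between the RNA types was not tested. Of 16 tested in nascent RNA, 15 were higher and none lower (16 adjusted over the list alone, median log2 1.14), among them Zscan4e (1.29), Zscan4b (1.25) and Zscan4f (0.99), which guard telomeres, and Pramel6 (0.58). The camera test gave adjusted p = 1.33e-06 (adjusted p = 0.0346 with an estimated correlation), and ERCC scaling left 9 higher and 0 lower. Zscan4 copies are so alike that reads are shared among them, so the family is better read than its members. Fibroblast feeder markers rose alongside: 11 of 15 higher and 0 lower, or 6 and 0 with ERCC scaling (11 adjusted over the list alone; median log2 0.72; camera adjusted p = 3.07e-08, adjusted p = 0.0164 with an estimated correlation). They were led by Acta2 (log2 1.60), Col1a2 (1.31), Col1a1 (1.18) and Col5a1 (0.71). Immediate early genes were higher with them, 11 of 19 higher and 0 lower, but 1 of 19 with ERCC scaling (11 adjusted over the list alone; camera adjusted p = 5.06e-04, adjusted p = 0.0435 with an estimated correlation), with Junb (log2 0.91), Jun (0.58), Ccn2 (0.53) and Ier2 (0.28). Among p53 targets 11 of 22 were higher and 5 lower, but 1 and 0 with ERCC scaling (19 adjusted over the list alone), with the exonuclease Aen (log2 0.88), the BH3 protein Pmaip1 (0.72) and Plk2 (0.62) up (camera adjusted p = 0.022, adjusted p = 0.12 with an estimated correlation).

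Ribosomal protein and naive pluripotency genes were lower in KO nascent RNA relative to total gene counts, though with ERCC scaling only 4 of 56 and 2 of 30 were lower. Of 56 ribosomal genes 38 were lower and 3 higher (44 adjusted over the list alone), with Rpl21 and Rpl34 at log2 -0.69 and Rplp0 at -0.37 (camera adjusted p = 5.54e-10, adjusted p = 0.245 with an estimated correlation), the reverse of steady nuclear RNA; without the 10 min libraries 31 were lower and 10 higher. Naive genes were 18 lower and 5 higher of 30 (23 adjusted over the list alone), with Fgf4 (log2 -0.44), Lifr (-0.28) and Tet2 (-0.26) down and Tfcp2l1 (0.24) up (camera adjusted p = 0.00915, adjusted p = 0.0837 with an estimated correlation). Long noncoding RNAs were 11 lower and 5 higher of 27 (16 adjusted over the list alone; 5 lower and 0 higher with ERCC scaling), led by Lncenc1 (log2 -0.67), Rian (-0.56) and Meg3 (-0.45; camera adjusted p = 0.00915, adjusted p = 0.299 with an estimated correlation). Mitochondrial transcripts were 6 lower of 15 (6 adjusted over the list alone; mt-Nd6 log2 -0.22; camera adjusted p = 2.11e-04, adjusted p = 0.329 with an estimated correlation), but 0 of 15 passed with ERCC scaling.

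Among lists that did not pass in nascent RNA, 5 had members past the threshold by total counts but 0 with ERCC scaling: m6A factors, nuclear decay factors, heterochromatin factors, Fto neighbours, and formative and primed pluripotency genes (5 higher and 5 lower of 14; 10 adjusted over the list alone). By total counts, m6A factors were 10 lower and 2 higher of 24 (12 adjusted over the list alone; Zc3h13 log2 -0.23), and nuclear decay factors and heterochromatin factors 11 lower and 4 higher of 24 and 29 (15 and 16 adjusted over the list alone). Of 6 Fto neighbours, Chd9 (log2 0.45) and Rbl2 (0.34) were up and Aktip (-0.30) down, 3 higher and 1 lower (4 adjusted over the list alone). Primitive endoderm genes split between the endocytic adaptor Dab2 (log2 1.55) and the laminin Lama1 (-0.67). The genotype effect differed between 60 and 10 min of labelling for 584 genes (287 higher, 297 lower, 49.1% higher; 2958 at unadjusted p < 0.05). RLE scaling put 60.8% of them higher (355 and 229), DESeq2 gave 200 higher and 79 lower, and with ERCC scaling edgeR called 0 (1693 at unadjusted p < 0.05). Without KO 10 min library 1 the count was 353, without KO 60 min library 2 325, and without WT 60 min libraries 1 and 2 295 and 344.

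**Figure D2:**
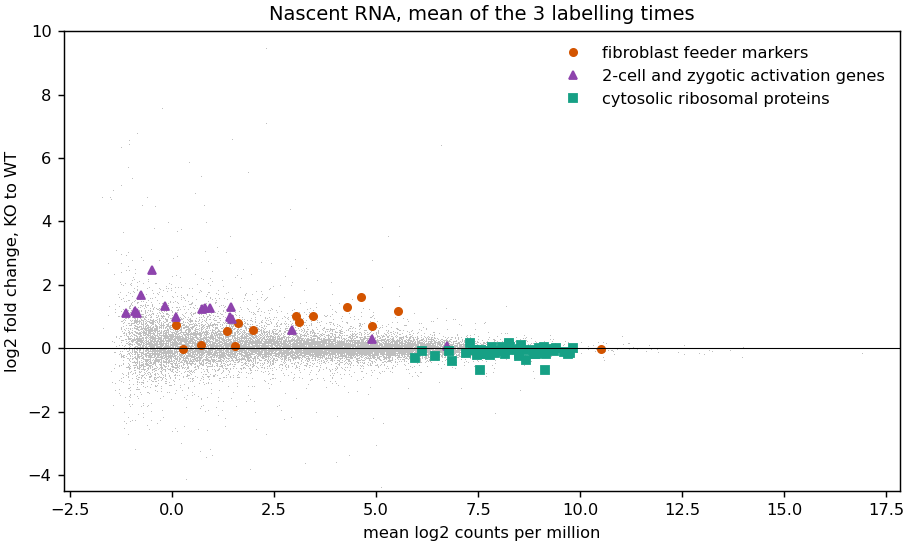
Log2 fold change of nascent RNA, KO to WT, against level, with fibroblast feeder markers, 2-cell genes and ribosomal protein genes marked over all genes. The first 2 groups lie mostly above 0 and ribosomal genes mostly just below it. With ERCC scaling 6 fibroblast markers and 9 2-cell genes are higher and 4 ribosomal genes are lower.

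ChIP peak lists of KO mESCs covered less of the genome for EP300, YY1, H3K4me3 and RNA polymerase II, and more for Mettl3. EP300, the enhancer acetyltransferase, covered 0.43 and 0.47 Mb in KO against 0.87 and 0.80 Mb in WT (log2 ratio -0.90, SD within genotype 0.09; 767 and 856 against 1623 and 1476 peaks). YY1, which loops enhancers to promoters, had a log2 ratio of -0.51 (SD 0.09), the promoter mark H3K4me3 -0.23 (SD 0.03), polymerase II -0.20 (SD 0.05) and the m6A writer Mettl3 0.36 (SD 0.05). In each of these 5, and in H3K4me1 and H3K9me3, both KO libraries lay on the same side of both WT libraries, the most extreme order that 2 against 2 allows. With the same number of peaks per list the ratios shrink to -0.16 for EP300, -0.25 for YY1, -0.16 for H3K4me3, -0.05 for polymerase II and 0.14 for Mettl3. Most of the difference for EP300, polymerase II and Mettl3, and part of it for YY1 and H3K4me3, is thus in how many peaks were called. Several lists were short. Mettl3 had 192 and 197 peaks in KO and 122 and 123 in WT, and YY1 555 and 473 against 666 and 624. Polymerase II had 1546 and 1643 against 1963 and 1897. Read depth and antibody enrichment, on which such numbers may depend, were not examined here.

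Other marks were less even between libraries. The enhancer mark H3K4me1 covered 69.0 and 34.5 Mb in KO and 97.7 and 103.1 Mb in WT (log2 ratio -1.04, SD 0.50), a ratio of -1.54 without KO library 1, -0.54 without KO library 2 and -1.55 at the stricter peak threshold. The heterochromatin mark H3K9me3 covered 46.4 and 54.5 Mb in KO and 57.5 and 56.8 Mb in WT (log2 ratio -0.19, SD 0.12). H3K20me3 had a log2 ratio of -0.16 (SD 0.22) and the active mark H3K27ac of 0.15 (SD 0.15). Each of these 3 ratios leaned on KO library 1: without it they were -0.069 for H3K9me3, 0.066 for H3K20me3 and 0.005 for H3K27ac. H3K20me3 and H3K27ac thus show no steady difference, and H3K9me3 kept its sign but not its size.

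**Figure D3:**
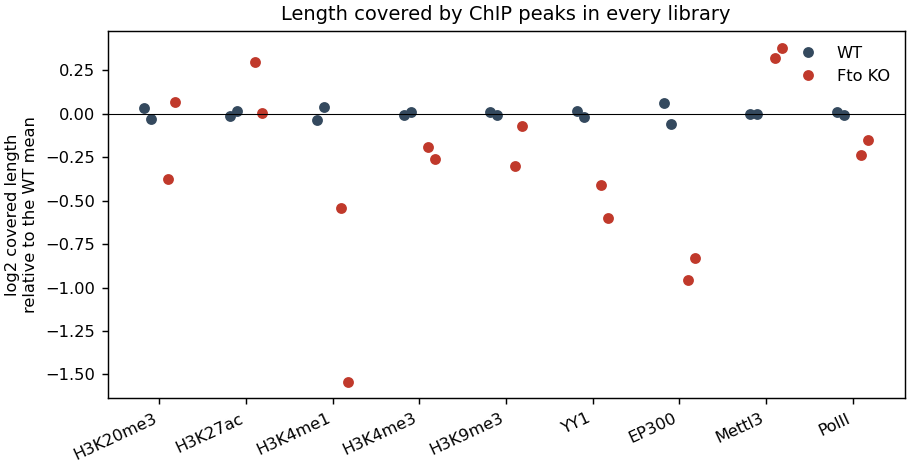
Length of the genome covered by ChIP peaks in each library, as log2 relative to the WT mean of the antibody. EP300, YY1 and H3K4me1 points of KO lie lowest, and the KO H3K4me1 libraries lie far apart.

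Single promoters had peaks in both libraries of one genotype and neither of the other. Some such sets were no larger than those of mixed KO and WT pairs. These were H3K27ac in WT only (1579 regions, mixed pairs 409 to 1672) and, in KO only, H3K4me1 (1002, 1136 to 4472), YY1 (34, 16 to 36), polymerase II (103, 68 to 107) and EP300 (13, 19 to 40). Genes named from these sets cannot be told from differences between lists. The H3K4me3 set in KO only was little larger than those of mixed pairs (1441, mixed pairs 1104 to 1218). H3K27ac appeared in KO only at the start of Pgpep1l (chromosome 7, 68255008 to 68264944), Zfp821 and the aldehyde oxidase Aox3, and in WT only at Alkbh7, Mpzl3 and Prr23a3. H3K4me3 appeared in KO only at the zinc finger repressor Zfp932 (chromosome 5, 109995705 to 109997749), H2-Eb1 and Trim10, and in WT only at Fam13a, Pnp2 and Pyurf. EP300 was at the uridine phosphorylase Upp1 (chromosome 11, 9116967 to 9117346), Src and Dmtn in WT only, and its WT-only regions (410, against 13 in KO) included Pou5f1. Polymerase II was at Gadd45g (chromosome 13, 51845832 to 51846729), Rhpn2 and Cfl1 in WT only and at Gtf2a1, Sema4b and Tmpo in KO only. H3K9me3 was at Mir3096, Ttyh3 and Nhlrc1 in WT only, among 2697 such regions, and at Slain1, Ighv10-3 and Hus1 in KO only. Its WT-only regions also covered 5 of 36 imprinted genes (Mcts2, Nnat, Peg10 and Sgce among them) and 4 of 26 germline genes (Brdt, Ddx4, Sycp1 and Tdrkh). These shares were not tested against that of all genes. H3K20me3 was at Slc7a15, Pink1 and Fkbp6 in WT only and at Cd209c, Vmn2r44 and Trim61 in KO only. H3K4me1 was at Senp5, Icam4 and Prickle4 in WT only and at Hmg20b, Nhej1 and Zfp572 in KO only. YY1 was at Szrd1, Ncdn and Daxx in WT only and at Rpa2, Mcmbp and Mau2 in KO only.

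Genes that gained H3K27ac at their start in KO cells had more nascent RNA there, relative to total gene counts. Of 386 such genes 156 (40.4%) were higher and 32 (8.29%) lower in nascent RNA, against 18.1 and 25.4% of all genes with an H3K27ac region at their start (camera adjusted p = 3.36e-08, adjusted p = 5.09e-04 with an estimated correlation). Their median log2 change was 0.18, against -0.028 for all genes with such a region. Sets from peak regions were not tested with ERCC scaling, which moved the median of all genes in nascent RNA by -0.20. The 96 genes with H3K27ac at their start in WT only were 33 lower and 6 higher (camera adjusted p = 0.0086, adjusted p = 0.0505 with an estimated correlation). Such regions were no more frequent than those of mixed KO and WT pairs (1579, mixed pairs 409 to 1672), so a loss is not shown beyond differences between lists. The 53 genes with H3K4me3 at their start in KO only were 24 higher and 6 lower (camera adjusted p = 1.63e-04, adjusted p = 0.0505 with an estimated correlation). These H3K4me3 regions were little more frequent than those of mixed KO and WT pairs (1441, mixed pairs 1104 to 1218). Many of them may thus be differences between lists. The 70 genes that lost H3K9me3 were 26 higher and 5 lower (camera adjusted p = 0.0324, adjusted p = 0.0942 with an estimated correlation). In nuclear RNA, genes that gained H3K27ac were 68 higher and 26 lower (camera adjusted p = 0.0084, adjusted p = 0.113 with an estimated correlation). Genes with caRNA m6A regions of one genotype did not pass with camera, and mRNA regions were not tested this way. With KO-only caRNA regions 312 (29.7%) were higher and 274 (26%) lower in nascent RNA (camera adjusted p = 0.645, adjusted p = 0.508 with an estimated correlation). With WT-only regions 313 (20.2%) were higher and 549 (35.4%) lower (camera adjusted p = 0.0973, adjusted p = 0.0505 with an estimated correlation). Of all genes with a caRNA m6A region, 20.5% were higher and 22.9% lower, so lower genes were more frequent in the WT-only set.

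**Figure D4:**
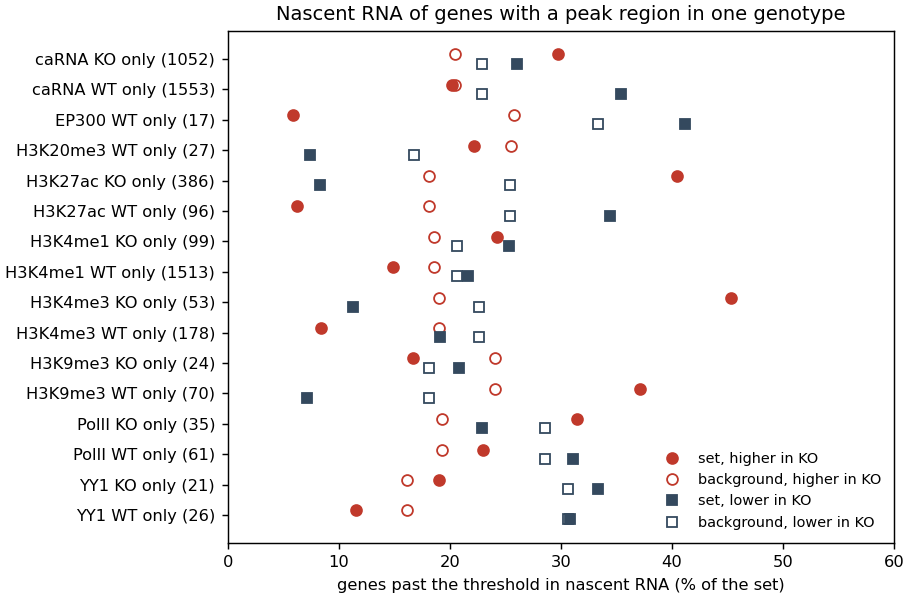
Share of genes past the threshold in nascent RNA for genes with a peak region in one genotype, beside the share of their background. Genes with H3K27ac or H3K4me3 regions of KO cells lie above their background among those higher in KO.

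Open chromatin was largely shared between genotypes. Of 140203 merged WT ATAC peaks, 71.2% (95% interval 70.9 to 71.4%) overlapped a KO peak, and of 143757 KO peaks 71.2% (71.0 to 71.4%) overlapped a WT peak. The lists are pooled, 1 per genotype, so no spread between libraries is known.

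KO GV oocytes lost some transcripts almost wholly and gained others. Bfsp1, a lens filament protein, changed by log2 -10.78 (SE 0.09; chromosome 2, 143826528 to 143863173), and Tox3, a chromatin factor, fell by 358-fold (chromosome 8, 90247040 to 90348343). The zinc carrier Slc39a8 fell by 171-fold and the splicing factor Cdc5l by 61.8-fold, and Spesp1, a sperm equatorial protein, was 661 times lower (counting interval 183 to 5460). Nfam1, an immune receptor, rose 99.9-fold, the chromatin factor Arid5b by log2 5.73, Pnpla3, a lipase, 32.5-fold, Zfp109 16.9-fold and the nucleosome binder Hmgn3 9.37-fold. In all, 7323 of 17019 genes passed (3843 higher, 3480 lower; 612 up and 760 down at least 2-fold; 2 libraries per genotype), with adjusted p = 2.42e-33 for Bfsp1 (edgeR quasi-likelihood). Scaled to ERCC spikes the median of all genes moved by -0.31 log2, and 1262 genes were higher and 9124 lower.

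Mitochondrial transcripts rose in KO GV oocytes: 13 of 15 higher and 0 lower (14 adjusted over the list alone; median log2 0.85), with mt-Nd5 (1.03), mt-Nd2 (0.98) and mt-Nd4l (1.06; camera adjusted p = 8.84e-15, adjusted p = 0.652 with an estimated correlation). Their share of counts was 1.76 and 1.91% in KO and 1.33 and 1.32% in WT. Ribosomal protein transcripts were 22 lower and 3 higher of 56 (25 adjusted over the list alone), or 56 and 0 with ERCC scaling, led by Rpl34 (log2 -0.95) and Rpl23 (-0.70; camera adjusted p = 0.00174, adjusted p = 0.652 with an estimated correlation). Heterochromatin and LINE-1 repressors were 12 lower and 4 higher of 29, or 24 and 0 with ERCC scaling (16 adjusted over the list alone), with the helicase Mov10 (log2 -1.03), Atrx (-0.67) and the corepressor Trim28 (-0.64) down (camera adjusted p = 0.0141, adjusted p = 0.652 with an estimated correlation). Primitive endoderm genes were 6 higher of 13, Dab2 (log2 0.66) and Lamc1 (0.44) among them, but 3 higher and 3 lower with ERCC scaling (6 adjusted over the list alone; camera adjusted p = 0.0261, adjusted p = 0.652 with an estimated correlation).

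Other lists in GV oocytes did not pass. Oocyte genes were 17 higher and 10 lower of 37 (29 adjusted over the list alone), flipping to 0 and 30 with ERCC scaling, with Ooep (log2 0.37) up and Oas1d (-0.36), Padi6 (-0.27) and Nlrp5 (-0.25) down. Deadenylation factors were 12 higher and 4 lower of 27 and m6A factors 11 and 8 of 24 (17 and 19 adjusted over the list alone), which turned to 2 and 17 and 2 and 18 with ERCC scaling. The Fto neighbours Rbl2 (log2 -2.24), Rpgrip1l (-1.39) and Aktip (-0.46) were down and Irx3 (1.55) up, 3 lower and 1 higher of 6 (5 adjusted over the list alone; camera adjusted p = 0.117). Activin subunits rose, Inhbb by log2 2.01 and Inhba by 1.88, while the immediate early Junb (-3.95) and Ier2 (-2.22) and the p53 target Pmaip1 (-2.29) fell.

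MII oocytes kept the loss of Tox3 but not that of Bfsp1. Bfsp1 rose by log2 10.05 (SE 0.22), the opposite of GV oocytes, while Tox3 was 313 times lower (counting interval 107 to 1520). Prr18 fell by 77.7-fold, Slc35d1, a nucleotide sugar carrier, was 83.8 times lower (14.7 to 3350), and the receptor Erbb2 and ubiquitin ligase subunit Fbxo6 were at least 13.2-fold and 7.35-fold lower. Klf8 was 14.7 times higher (4.68 to 74.5), and the cytokine inhibitor Cish, the lipase Mgll and Sync at least 5.67-fold, 4.15-fold and 3.4-fold higher, all from few counts. In all, 4878 of 20316 genes passed (2489 higher, 2389 lower; 2 libraries per genotype), with adjusted p = 1.51e-14 for Bfsp1 (edgeR quasi-likelihood). Without KO library 1 the count was 2772 and without KO library 2 2980.

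Ribosomal protein transcripts fell in KO MII oocytes and cytoplasmic deadenylation and mRNA decay factors rose. Of 56 ribosomal genes 41 were lower and 1 higher (46 adjusted over the list alone; median log2 -0.38), with Rpsa (-0.99), Rps2 (-0.68) and Rps7 (-0.68; camera adjusted p = 1.20e-20, adjusted p = 0.256 with an estimated correlation). Deadenylation and mRNA decay factors were 17 higher and 1 lower of 27 (18 adjusted over the list alone), led by the decapping factor Dcp1a (log2 0.86), the deadenylase Cnot6l (0.70), Tob2 (0.69) and Pan2 (0.65; camera adjusted p = 3.55e-07, adjusted p = 0.1 with an estimated correlation). Among m6A factors 12 were higher and 3 lower of 24 (15 adjusted over the list alone), among them the readers Igf2bp3 (log2 0.64), Ythdf3 (0.61), Igf2bp2 (0.44) and Ythdc1 (0.43; camera adjusted p = 3.12e-04, adjusted p = 0.12 with an estimated correlation). Beside them, cumulus and granulosa markers were 10 lower and 1 higher of 21 (11 adjusted over the list alone; median log2 -0.83), with Sfrp4 (-2.10), Gja1 (-1.13) and Ptx3, 99.1 times lower (33.6 to 483), though the list did not pass (camera adjusted p = 0.0671). Oocyte genes were 18 lower and 8 higher of 37 (27 adjusted over the list alone; camera adjusted p = 0.258), with Padi6 (log2 -0.49) and Nlrp14 (-0.46) down and Omt2b (1.00) up. Trophectoderm genes were 7 higher and 1 lower of 16 (8 adjusted over the list alone; camera adjusted p = 0.0622), with Gata3 (log2 1.37) up and Tead4 13.2 times lower (4.25 to 66.6). ERCC counts were too few here to set a scale.

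KO morulae carried more oocyte transcripts and less of the trophectoderm programme than WT morulae. The germ cell helicase Ddx4 rose 5.47-fold (log2 2.45, SE 0.13), the oocyte growth factor Gdf9 2.47-fold, Btg4, an adaptor for maternal mRNA decay, 2.6-fold and Oog1 3.61-fold. The keratins Krt8 and Krt18 fell by 2.76-fold and 2.78-fold, Lrp2 by 3.09-fold, Gata3, a trophectoderm transcription factor, by 2.26-fold and the pluripotency factor Nanog by 3.13-fold. In all, 4099 of 20316 genes passed (2032 higher, 2067 lower; 2 libraries per genotype), with adjusted p = 6.40e-10 for Ddx4 and 5.57e-08 for Nanog (edgeR quasi-likelihood). With ERCC scaling the median of all genes moved by -0.23 log2, and 1248 were higher and 4942 lower; that fit holds the morula libraries alone, which without ERCC scaling gave 2424 and 2441. Without WT library 2 the count was 2436. The genes with the steepest changes had few counts: Scel, Serpinb1c, Lrrtm3, Rassf6 and Cd200 were at least 5.96-fold, 5.68-fold, 4.26-fold, 3.12-fold and 2.84-fold higher. Egfl6, Mat1a and Wnt7a were at least 3.13-fold and Fmo6 at least 2.74-fold lower.

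Oocyte and maternal effect genes were 26 higher and 1 lower of 37 (30 adjusted over the list alone; median log2 0.98; camera adjusted p = 8.43e-18, adjusted p = 0.0237 with an estimated correlation), and in the fit of morulae alone 22 higher and 1 lower of 33, or 19 and 1 with ERCC scaling. Germline genes were 12 higher and 0 lower of 24, and in the fit of morulae alone 12 and 2 of 22, or 10 and 5 with ERCC scaling, with Dazl (log2 2.07) and Sycp2 (1.45; 14 adjusted over the list alone; camera adjusted p = 0.00138, adjusted p = 0.0989 with an estimated correlation). Genes of the 2-cell stage were 9 higher and 2 lower of 26, with Tdpoz5 (log2 2.69), Tdpoz4 (2.39) and Spz1 (1.98; 12 adjusted over the list alone; camera adjusted p = 0.00401, adjusted p = 0.0989 with an estimated correlation). Among p53 targets 9 of 22 were higher and 0 lower, and in the fit of morulae alone 12 and 1 of 20, or 6 and 3 with ERCC scaling, Perp (log2 0.88) and Trp53inp1 (0.75) among them (11 adjusted over the list alone; camera adjusted p = 0.00204, adjusted p = 0.0989 with an estimated correlation). Mitochondrial transcripts were 6 higher of 15, such as mt-Nd3 (log2 0.59), and in the fit of morulae alone 7 higher and 0 lower, or 4 and 4 with ERCC scaling (6 adjusted over the list alone; camera adjusted p = 0.00204, adjusted p = 0.655 with an estimated correlation).

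Trophectoderm genes were 9 lower and 2 higher of 16 in KO morulae (11 adjusted over the list alone; median log2 -0.55; camera adjusted p = 0.0017, adjusted p = 0.0989 with an estimated correlation). Primitive endoderm genes were 7 lower and 1 higher of 13, with Dab2 (log2 -1.28) and Lamc1 (-0.87) down and Gata4 (2.31) up (8 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.166 with an estimated correlation). Ribosomal genes were 13 lower and 2 higher of 56, and in the fit of morulae alone 17 and 7, or 41 and 0 with ERCC scaling, led by Rplp0 (log2 -0.79; 18 adjusted over the list alone; camera adjusted p = 0.0161, adjusted p = 0.763 with an estimated correlation), a call lost with RLE scaling. Naive genes were 7 higher and 9 lower of 28, and in the fit of morulae alone 8 and 9, or 5 and 15 with ERCC scaling (16 adjusted over the list alone), with Klf2 (log2 1.19) up and Tet2 (-0.95) and Tfcp2l1 (-0.61) down beside Nanog. The DNA methylation cofactors Dnmt3l (log2 -1.15) and Uhrf1 (-0.85) and the imprinted Meg3 (-2.58) fell. The effect of genotype differed between morulae and MII oocytes for 4070 genes (2005 higher, 2065 lower in morulae).

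**Figure D5:**
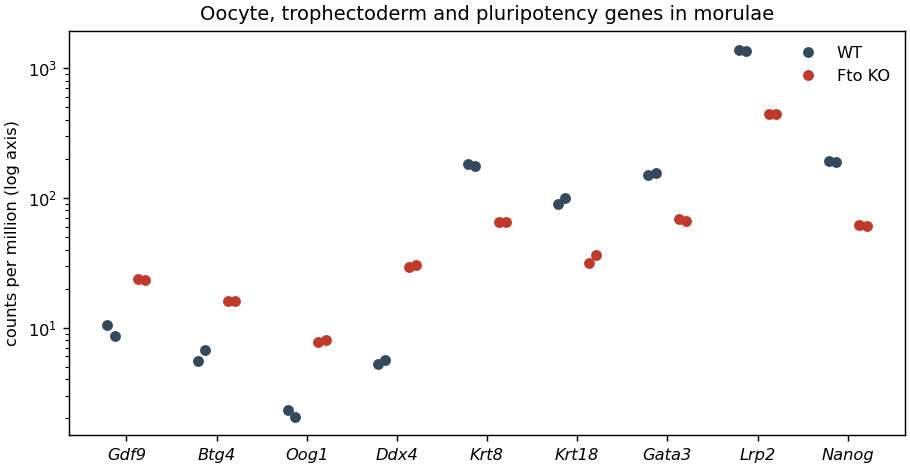
CPM of oocyte genes (Gdf9, Btg4, Oog1, Ddx4), trophectoderm genes (Krt8, Krt18, Gata3, Lrp2) and Nanog in each morula library. Oocyte genes are higher and the others lower in both KO libraries, on a scale relative to total gene counts; directions do not flip with ERCC scaling.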

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

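The tests of splits of the m6A lists, of trophectoderm levels, of the segment around Fto, of signs shared by GV and MII oocytes, and of fibroblast genes in paired RNA types were chosen only after the result was seen. So were the look at abundant oocyte transcripts and the look without Gm genes, and the reading of 3 tests was changed after their values were known, as stated at each. The others were written before their results were seen.

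KO morulae held more oocyte transcripts and less trophectoderm RNA. Oocytes or unfertilised eggs mixed into the KO samples would lift all oocyte transcripts by one share, and the ratio of the 75th to the 25th percentile of the implied share was 7.63 (5.35 to 13.8) over 432 transcripts, beyond the bound of 3 set beforehand. Low transcripts add counting noise to this. The 24 with at least 1000 CPM in KO MII oocytes, all higher in KO morulae, implied shares from 0.0183 to 2.33%. Their ratio of 2.84 (1.76 to 4.29) lay below the bound of 3, so the test is read as undecided although all 432 together met the bound. The oocyte profile is also assumed, so a mixture of oocytes or from another source stays open. Trophectoderm genes lay at a median log2 change of -1.13 (-1.475 to 0.599 over 9 genes), where a mixture predicts -0.007, too wide an interval to decide. In a fit of morulae alone, 22 of 33 oocyte genes were higher and 1 lower, and 19 and 1 with ERCC scaling. ERCC scaling moved the median of all genes by -0.23 log2. The test of scaling by total counts is undecided by its bounds set beforehand, but these values argue against scaling alone for those 19 genes. Slower embryos that keep maternal RNA longer, an effect of Fto on RNA decay, and the second gene that the DKO title might mean were not tested, and cannot be told apart here.

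Some genes in GV oocytes were nearly on in one genotype and off in the other. Of genes within 10 Mb of Fto with a mean log2 CPM of at least 2, the level also used for the pairs below, 9 of 97 changed at least 2-fold, 3.07 times the share elsewhere (304 of 10058; odds ratio 3.28, 1.44 to 6.6; Fisher's exact p = 0.00296), and of all tested genes 28 of 152 did, 2.32 times the share elsewhere (1338 of 16828; p = 3.09e-05), with Tox3, Rbl2 and Rpgrip1l among them, which a strain segment around Fto or an effect of the deletion on its neighbours may explain for those genes. Other strain segments would cluster the rest, and 3 neighbouring pairs were found (random draws: median 1, 95th percentile 2), but all lie in one chromosome 7 group of Gm paralogs that share reads, and without Gm genes there were 0, so this stays undecided although it met the bound set beforehand. One effect of losing Fto shared by both oocyte stages would keep signs, while 25% (5 of 20, 8.66 to 49.1%) turned, Bfsp1 among them; this is too few genes to exclude it. The strain background and the females used are not given in the sources used here.

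Fibroblast genes were higher in nascent RNA of KO cells. More fibroblast-like cells in KO cultures might raise them equally in nuclear RNA, yet the median difference, nascent minus nuclear, was 0.597 (0.372 to 0.878; 11 genes, 10 of them with a log2 change above 0 in nuclear RNA). The 11 genes were those that passed as higher in nascent RNA, a choice that favours a gap in this direction. Nascent and nuclear RNA came from other cultures with possibly other cell shares, so this gap alone excludes nothing, although it met the bound set for the test. Differentiation of some mESCs, and serum response shared with immediate early genes, stay open and were not tested.

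Of the 12 nascent libraries, 1 of 100 splits within labelling times, the real one, reached 7818 genes, and the highest other reached 2164. The splits cover only the spread between these libraries. Replicates may be technical, so a difference between single WT and KO cultures unrelated to Fto is not excluded. For the caRNA m6A lists the real split gave 4697 one-genotype regions and the highest other 1576, 1 of 10 splits, which are too few for a share under 0.05.

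The change over 6 h of actinomycin D differed between genotypes for 135 genes, the genotype effect differed between labelling times for 584 and between morulae and MII oocytes for 4070. H3K27ac lists of KO cells held 203 and 107 peaks on Drosophila sequences, against 48 and 54 in WT, and the use of this DNA is not described in the labels. The m6A control RNA peak had a mean fold of 2.33 in KO caRNA lists (SD 0.26) and 1.61 in WT (SD 0.07, n = 3). ERCC counts reached 40.0% of a 10 min nascent library. With 0 groups of 4 or more samples, no sample could be tested as an outlier within its group.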

How the results depend on the processing

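ERCC scaling, nascent RNA without the 10 min libraries, the level of named genes in MII oocytes alone and all tested genes around Fto were chosen after seeing the data. The other alternatives were planned. The cause was not tested for any of the shifts below.

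With ERCC scaling, nuclear RNA at 0 h gave 2291 genes in place of 3711, the decay difference 47 in place of 135, nascent RNA 1469 in place of 7818, and morulae 6190 in place of 4099, where the fit of morulae alone gives 4865 without ERCC scaling. The labelling-time difference gave 0 with edgeR (1693 at unadjusted p < 0.05) and 279 with DESeq2, in place of 584. GV oocytes gave 4838 with DESeq2 in place of 7323. The decay difference gave 451 genes without a filter on low counts. With a replicate block it gave 934, but replicate numbers state no pairing, and residuals of equal numbers correlated at 0.172 to 0.222 in nuclear RNA, over 2 numbers only. The block also made 5 lists pass: trophectoderm, heterochromatin and nuclear decay factors in nuclear RNA at 0 h (adjusted p = 0.049 each), ribosomal proteins in the decay difference (0.00269) and Fto neighbours in GV oocytes (6.21e-04).

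With ERCC scaling these genes turned from higher to lower: in nascent RNA Hnrnpa2b1 (-0.072), Zc3h18 (-0.070) and Rpgrip1l (-0.008), in GV oocytes Dnmt3l (-0.019), Gata4 (-0.048), Lamb1 (-0.199), Nr5a2 (-0.033), Exosc9 (-0.020), Dcp1a (-0.074), Cnot1 (-0.112), Tob2 (-0.114) and Mdm2 (-0.020), and Fto over 6 h of actinomycin D in WT (-0.616).

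Leaving out each library in turn gave 2243 to 2556 genes in nuclear RNA at 0 h and 18 to 152 for the decay difference. It gave 7108 to 7500 in nascent RNA, 295 to 577 for the labelling-time difference, 5931 to 6713 in GV oocytes, 2772 to 4663 in MII oocytes and 2436 to 2853 in morulae. Counts moved by more than 1.5 times in nuclear RNA without KO library 1 (2243), KO library 2 (2418) or WT library 2 (2434), in MII oocytes without KO library 1 (2772) or 2 (2980), and in morulae without WT library 2 (2436). For the decay difference these libraries were KO 0 h library 1 (65) and 2 (23), WT 0 h library 1 (41) and WT 6 h libraries 1 (18) and 2 (21), and for the labelling-time difference KO 10 min library 1 (353), KO 60 min library 2 (325) and WT 60 min libraries 1 (295) and 2 (344). One-genotype m6A regions were 2860 to 4304 in KO and 3819 to 5570 in WT caRNA, and 1231 to 3983 in KO and 1199 to 4350 in WT mRNA, since the rule loosens with each list left out. Covered length of H3K4me1 ran from a log2 ratio of -1.541 to -0.540, H3K9me3 from -0.301 to -0.069, H3K20me3 from -0.378 to 0.066 and H3K27ac from 0.005 to 0.299, and EP300 from -0.960 to -0.834.

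The same number of peaks per list gave 491 KO-only and 470 WT-only mRNA regions in place of 890 and 918. It shrank the covered-length ratios of H3K4me3 to -0.162, YY1 to -0.253, EP300 to -0.156, Mettl3 to 0.138 and polymerase II to -0.047, and the stricter threshold took H3K4me1 to -1.549. Shared ATAC peaks (WT, then KO) were 69.26 and 83.05% at the stricter threshold, 64.93 and 67.16% when at least 50% of the peak had to overlap, and 72.29 and 70.48% with equal numbers of peaks, in place of 71.17 and 71.2%.

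Of 137 tests of gene lists 32 passed, 4 with an estimated correlation and 53 with fry. Of 48 tests of peak gene sets 5 passed, 1 with an estimated correlation and 24 with fry. Without the 10 min libraries 6477 genes passed in nascent RNA, and 5873 of them also passed with them, all with the same sign.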

Other observations

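Only the look at the total RNA level was chosen after the result was seen; it used the ERCC counts. The log2 ratio of gene to ERCC counts, KO minus WT, was -0.26 in GV oocytes and -0.23 in morulae, where exact permutation tests of 2 against 2 cannot pass 0.05. It was -0.25 in nascent RNA (exact permutation p = 0.213) and -0.014 in nuclear RNA at 0 h (exact permutation p = 1). In nascent RNA it was lower in KO after 30 and 60 min, while after 10 min the KO libraries stood at 1.28 and 0.88 and the WT libraries at 1.24 and 0.59. Over 6 h of actinomycin D it fell by 0.74 in WT and by 0.96 in KO nuclei.

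Some neighbours of Fto changed in mESCs and oocytes. Chd9 was higher in nascent RNA (log2 0.45), nuclear RNA (0.47) and MII oocytes (1.03), whereas Rbl2 was higher in nascent RNA (0.34) and lower in GV (-2.24) and MII oocytes (-1.50), and Rpgrip1l was lower in GV (-1.39) and MII oocytes (-1.14).

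The imprinted Peg3 was lower in KO nuclear RNA (log2 -1.08) and nascent RNA (-0.78) and higher in GV (0.78) and MII oocytes (1.08). The trophectoderm factor Gata3 was higher in MII oocytes (1.37) and lower in morulae (-1.18).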
